A study of Homo sapiens with 96 samples.

How the data were processed

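Single WM266.4 cells were captured on a Fluidigm C1 chip, imaged, amplified with SMART-Seq v4 and made into libraries with Nextera XT, per the labels' protocols. The deposited values are FPKM per gene and cell, made by the authors with TopHat2 2.0.9 and Cuffnorm 2.2.1 on GRCh38, per the submitters' processing notes. The unit was taken from the values, whose sums per cell ranged from 699760.0 to 15646628, and from the use of Cuffnorm. The annotation release was not given in the sources used here. SMART-Seq v4 does not mark strand, so overlapping genes on opposite strands share fragments.

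Each of 96 tables listed 58024 gene IDs, of which 57375 matched GENCODE 29 on GRCh38 once version numbers were dropped, and symbols and coordinates come from there. The 649 others held 0.0577% of all FPKM. Relative depth was read from the lowest FPKM of genes with 1 annotated transcript, multiplied by its length, and fragment counts themselves were not used. A cell in which 1 fragment at 1 kb was worth over 2 FPKM was called shallow, a limit chosen after seeing the data. The value of 1 fragment also depends on how FPKM was scaled in each cell. No cell was removed by its number of genes, since all 96 had at least 4000.

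A gene was called detected at 1 FPKM, and 13014 genes with a mean of at least 1 FPKM that were detected in at least 10 cells entered the analyses across cells, as log2(FPKM + 1). Co-variation was the mean pairwise Spearman rho of a list with at least 4 such genes, ranked among 10000 random lists of the same size matched on mean level in 20 bins. List scores were means of centred log2 values minus 50 matched control genes per member, and Pearson r between scores was ranked among 10000 pairs of random lists without shared genes. A list stood apart above percentile 99, and a pair below 0.5 or above 99.5. Such percentiles describe these libraries and are not p-values. Spread was the squared coefficient of variation against the mean, as the residual from a running median over 101 genes. Cells were clustered by Ward's method on 500 genes, with doublets left to the imaging of the chip. Shares of cells have exact Clopper-Pearson intervals at 95%, which cover counting error only.

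The gene lists and pairs of the Results, the percentile and detection limits and the rule for named genes were fixed before the data were examined. The limit for shallow cells was not. The ER and lysosomal lists and the pairs under Other observations were added later. Named were 15 melanoma and cycling genes, the 4 most abundant members of each list, the 3 highest and the lowest members by mean rho in lists that stood apart, the 25 most spread genes, 10 genes on each side of 3 scores, and the 2 most detected markers of each cell type. MSMP, MT-RNR2 and markers listed at 0 were named in places after their values were seen. Alternatives covered detection limits, pseudocounts, gene and cell filters, TPM, regression on genes detected, variance of log2, k-means and 2000 genes, and their effect is given separately. For the followers of a score, a shift was called small when below the median difference between odd-numbered and even-numbered cells, a limit set after the data were seen.

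The methods were tested on simulated data, made from the 13014 genes by shuffling each over cells and planting common factors. Of 200 lists without a factor, 3 passed the limit, and of 10 lists planted at a rho of 0.0478, 9 did, with a median of 0.0390, so that rho came out somewhat low. All 10 pairs planted with opposite factors were found, at a median r of -0.641. They were planted at the same strength, so finding weaker pairs was not tested. The opposite pairs that stood apart in the real cells had r from -0.523 to -0.366. Shuffling removed the co-variation that random lists hold in the real data. There, their 99th percentile lay between 0.0409 and 0.173, and MAPK output at a rho of 0.0520 did not pass. These rates therefore hold for shuffled data only. Of 200 genes given extra spread, the residual of 156 rose by over 0.1 log10 units, against 0 of the 12814 others. With the variance of log2, 133 of the 200 and 94 of the others rose by over 0.1 squared log2 units. Each rise was counted from the residual of the same gene before planting. The values of the others were left unchanged, so only shifts of the running median could move them. The ranking of genes by spread was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.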

Results

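Single-cell RNA sequencing was available for 96 WM266.4 cells, a human melanoma line with a BRAF mutation and a hemizygous PTEN deletion that carried EGFP and firefly luciferase. The cells had been recovered from the brains of nude mice 20 days after injection into the heart, and had attached to plastic during 1 h of culture. All 96 cells formed a single group, and no animal was named for any cell, so the group counted as 1 sample of cells. No second group was present, no batch of cells was labelled, and no p-values were made from cells.

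The number of genes at 1 FPKM or more had a median of 8520.5 per cell and ranged from 4975 to 9937. Depth, as far as it can be read from FPKM, differed between cells. The value of 1 fragment on a transcript of 1 kb, read from the lowest steps of the values, had a median of 0.685 FPKM and ranged from 0.331 to 54.8 FPKM. In 10 cells it exceeded 2 FPKM, and these are called shallow, against 86 deeper cells. The value also depends on how FPKM was scaled in a cell, and FPKM totals ranged from 699760.0 to 15646628. Shallow and deeper therefore refer to this value, not to the number of fragments alone. Cell 9 was the shallowest by this value. It had 4975 genes and 78.6% of its FPKM from mitochondrial genes, where the median over all cells was 12.0%. Of the 7 cells above 30% mitochondrial, 5 were shallow.

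**Figure D1:**
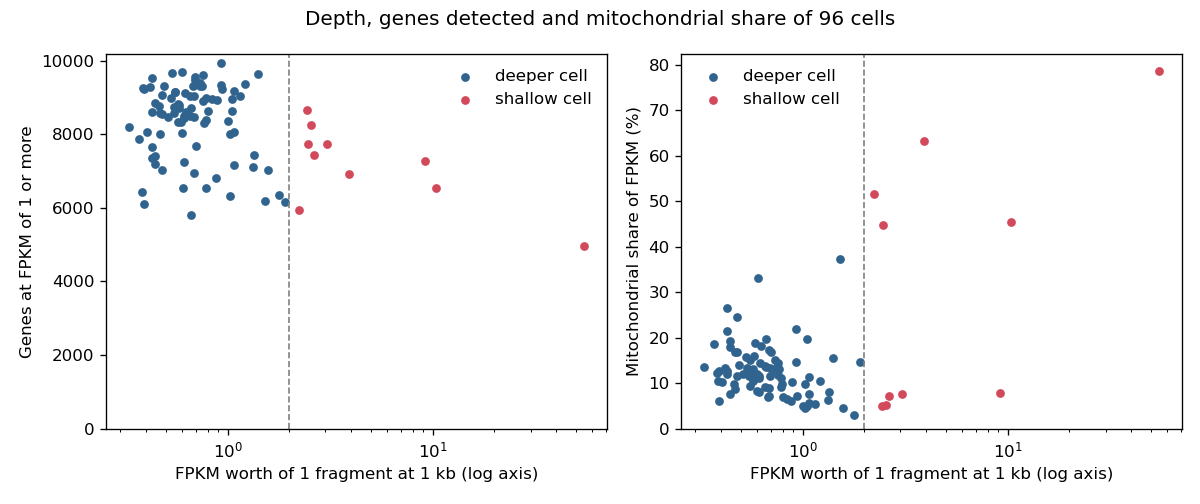
Genes at 1 FPKM or more (left) and mitochondrial share of FPKM in percent (right) against the FPKM worth of 1 fragment at 1 kb (log axis), 1 point per cell. The dashed line at 2 FPKM separates 86 deeper cells from 10 shallow cells, and cell 9 lies at the far right.

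Whether recovered tumour cells kept a melanocytic identity was described from 27 lineage genes. SOX10, MITF and TYR were detected in every cell, while other genes of the pigment pathway varied widely, and 18 of the 27 were detected in at least 50% of cells. SOX10, a neural crest transcription factor (ENSG00000100146.16, chromosome 22, 37970686 to 37987422), was at 1 FPKM or more in 96 of 96 cells (median of 26.9 FPKM, interquartile range 15.5 to 39.8). MITF, the central regulator of the melanocyte lineage (ENSG00000187098.14, chromosome 3, 69739435 to 69968337), was detected in 96 of 96 cells (median of 334 FPKM, interquartile range 136 to 673), as was TYR, the tyrosinase of melanin synthesis (ENSG00000077498.8, chromosome 11, 89177452 to 89295759; median of 285 FPKM, interquartile range 152 to 412). PMEL, a structural protein of melanosomes (ENSG00000185664.14, chromosome 12, 55954105 to 55973317), was detected in 90 of 96 cells (93.8%, interval 86.9 to 97.7%), with a median of 38.9 FPKM, interquartile range 7.03 to 318, and a highest value of 10146 FPKM. DCT (ENSG00000080166.15, chromosome 13, 94436808 to 94479682) reached 1 FPKM in 63 of 96 cells (median of 8.46 FPKM, interquartile range 0.148 to 45.5), MLANA (ENSG00000120215.9, chromosome 9, 5890802 to 5910606) in 36 of 96 cells (median of 0 FPKM, interquartile range 0 to 15.2) and TYRP1 in 4 of 96 cells. S100B (median 492 FPKM) and GPNMB (median 297 FPKM) were detected in 96 of 96 cells each.

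Genes of the dedifferentiated melanoma state differed in detection, with 10 of 23 in at least 50% of cells. NGFR, a neural crest receptor (ENSG00000064300.8, chromosome 17, 49495293 to 49515017), was detected in 84 of 96 cells (87.5%, interval 79.2 to 93.4%; median of 35.2 FPKM, interquartile range 8.94 to 72.2), and AXL, a receptor tyrosine kinase (ENSG00000167601.11, chromosome 19, 41219203 to 41261766), in 22 of 96 cells (22.9%, interval 15.0 to 32.6%; highest value 66.7 FPKM). EGFR, the epidermal growth factor receptor, was listed at 0 in all 96 cells, which does not show that EGFR was absent, since transcripts of low abundance can be missed in single cells. VIM (median 1031 FPKM), CTGF (137 FPKM), CYR61 (84.4 FPKM) and FOSL1 (70.5 FPKM) had the highest means of that list. Intervals are exact binomial at 95% and cover the counting of cells only.

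**Figure D2:**
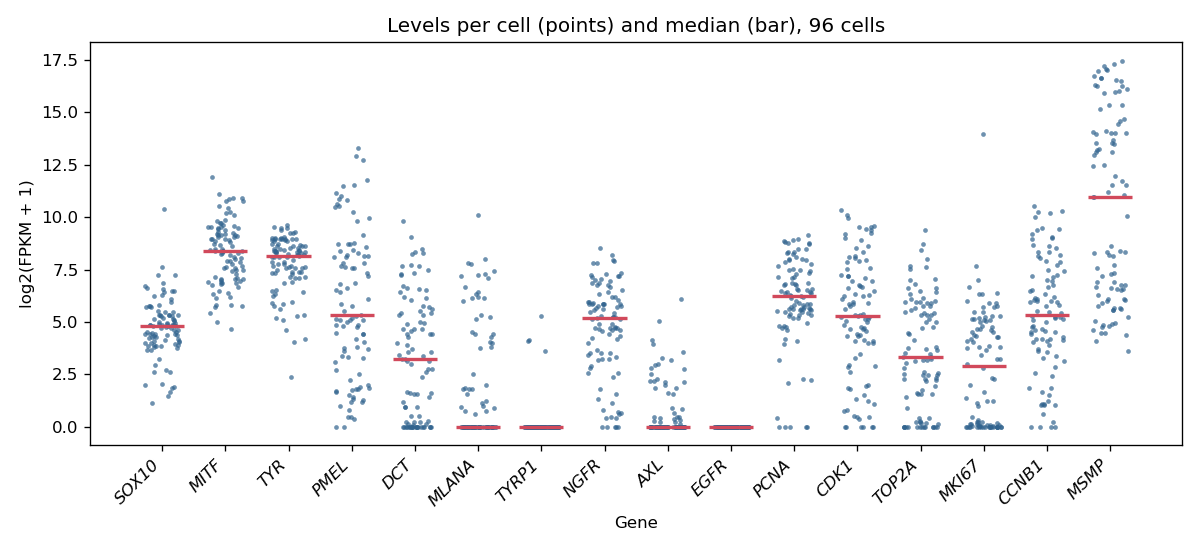
Level of the named genes as log2(FPKM + 1) in each of the 96 cells (points), with the median as a bar. MITF, SOX10 and TYR lay above 0 in all cells, EGFR at 0 in all, and MSMP spanned from 11.2 to 178275 FPKM.

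Cycling genes were detected in most cells, and 27 of 30 G2/M genes and 22 of 26 G1/S genes were found in at least 50% of cells. PCNA, the sliding clamp of DNA replication, was detected in 90 of 96 cells (median of 73.9 FPKM, interquartile range 40.7 to 176), the cyclin B1 gene CCNB1 (ENSG00000134057.14, chromosome 5, 69167010 to 69178245) in 90 of 96 cells (median of 39.8 FPKM, interquartile range 11.9 to 173) and the mitotic kinase CDK1 (ENSG00000170312.15, chromosome 10, 60778331 to 60794852) in 84 of 96 cells (median of 38.5 FPKM, interquartile range 8.20 to 147). TOP2A was detected in 73 of 96 cells (median of 9.13 FPKM, interquartile range 1.87 to 52.9) and MKI67 in 58 of 96 cells (median of 6.51 FPKM, interquartile range 0.0481 to 31.5), with its highest value in cell 9. All 5 genes were detected together in 51 cells (53.1%, interval 42.7 to 63.4%), and no cell lacked all 5. Of the 30 G2/M genes, at least 25 were detected in 42 cells and at most 15 in 22 cells.

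Of 21 gene lists fixed in advance, 13 varied together across cells more than matched random lists did. The mean pairwise Spearman rho was highest for mitochondrially encoded genes (0.728), G2/M genes (0.593), G1/S genes (0.418) and cytosolic ribosomal protein genes (0.402). Within the G2/M list, NDC80 (0.679), UBE2C (0.678) and HMGB2 (0.672) had the highest mean rho to the other members and CKS2 (0.231) the lowest, while CKS2 (median 732 FPKM), HMGB2 (248 FPKM), UBE2C (39.4 FPKM) and CKS1B (307 FPKM) had the highest means. In the G1/S list, CLSPN (0.537), PCNA (0.521) and CDC6 (0.519) led and NASP (0.301) was lowest. NASP (median 247 FPKM), TYMS (182 FPKM) and RFC2 (81.8 FPKM) were abundant members. MT-ATP6, MT-CO3 and MT-ND4 led the mitochondrially encoded list, with MT-CO1 lowest (0.661), and MT-CO2 (median 12473 FPKM) and MT-ATP8 (11029 FPKM) were among its most abundant. Ribosomal protein genes, whose processed copies make single members uncertain, were led by RPS18, RPL32 and RPS3, with RPL7 lowest (-0.0337), and RPS18 (median 3674 FPKM), RPS19, RPS15 and RPS2 were most abundant.

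Immediate-early genes (0.253), melanocytic genes (0.233) and cholesterol synthesis genes (0.202) also stood apart. FOS (median of 993 FPKM, interquartile range 706 to 1478) and EGR1 (median of 177 FPKM, interquartile range 127 to 251), transcription factors induced within minutes of stimulation, were detected in 96 of 96 cells each and, with JUND, led their list, while EGR3 had a mean rho of -0.00898. IER3 (median 138 FPKM) and JUNB (65.8 FPKM) were the next most abundant. DCT (0.387), MITF (0.385) and PMEL (0.379) led the melanocytic list and S100A1 (-0.0866) was lowest. MSMO1, INSIG1 and IDI1 led the cholesterol list, LSS (-0.0126) was lowest, and FDFT1 (median 279 FPKM), IDI1 (163 FPKM), FDPS (99.9 FPKM) and LDLR (50.2 FPKM) were most abundant. Lower values that still stood apart were found for the MHC class I and interferon (0.105), glycolysis and hypoxia (0.0976), extracellular matrix (0.0925), nuclear-encoded OXPHOS (0.0907), dedifferentiated (0.0879) and ER stress (0.0664) lists. Their leading members were IFITM3, BST2 and ISG15 (lowest STAT1), ALDOA, ENO1 and PGAM1 (lowest P4HA1), TNC, TIMP1 and COL6A1 (lowest MMP2), COX5B, COX6B1 and COX7C (lowest ATP5F1B), TNC, NGFR and SERPINE1 (lowest CYR61), and HSPA5, XBP1 and PDIA4 (lowest PSAT1), in that order of lists. After rescaling to TPM, the dedifferentiated (0.101), extracellular matrix (0.110) and ER stress (0.122) lists no longer stood apart from random lists, and OXPHOS did not in the 86 deeper cells (0.0675). The ER stress call was also lost with the stricter gene filter and with the genes detected regressed out.

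Abundant members of these lists were B2M (median 4497 FPKM), IFITM3 (563 FPKM) and BST2 (207 FPKM) for antigen presentation and interferon, with IFITM1 in 72 of 96 cells. For glycolysis they were ENO1 (1508 FPKM), LDHA (1612 FPKM), TPI1 (1034 FPKM) and ALDOA (889 FPKM), and for OXPHOS COX7A2 (1127 FPKM), NDUFS5 (1105 FPKM), UQCRQ (940.4 FPKM) and COX8A (798 FPKM). TIMP1 (2118 FPKM), SPARC (1112 FPKM), FN1 (506 FPKM) and CD44 (299 FPKM) led the matrix genes, and HSP90B1 (467 FPKM), ATF4 (427 FPKM), XBP1 (345 FPKM) and DDIT3 (246 FPKM) the ER stress genes. All values in this paragraph are medians over 96 cells.

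The other 8 lists did not exceed the percentile of 99, namely MHC class II (mean rho 0.136), cancer-testis and melanoma antigens (0.0727), p53 and apoptosis (0.0556), MAPK output (0.0520), heat shock (0.0436), fatty acid synthesis (0.0380), neuronal and synaptic genes (0.0333) and brain colonisation (0.0315). With the genes detected regressed out, MHC class II (0.209) and brain colonisation (0.0572) stood apart, and in TPM heat shock did (0.203). SERPINE2, a serpin of the brain colonisation list, had a median of 1535 FPKM and was detected in 96 of 96 cells, and PLAT, the tissue plasminogen activator, had a median of 87.0 FPKM in 96 of 96 cells. VEGFA was detected in 89 of 96 cells. CCND1 (median 150.2 FPKM), ETV5 (87.8 FPKM) and DUSP6 (79.9 FPKM), readouts of MAPK signalling, were each detected in 94 of 96 cells, and EPHA2 in 78 of 96 cells. TUBB3 was detected in 91 of 96 cells, MAP2 in 83 of 96 cells, NLGN1 in 70 of 96 cells and ENO2 in 64 of 96 cells. GDF15 (median 201 FPKM), CDKN1A (116 FPKM), PMAIP1 (58.9 FPKM) and MDM2 (35.4 FPKM) led the p53 list, HSPA8 (814 FPKM), HSP90AB1 (733 FPKM), HSP90AA1 (642 FPKM) and DNAJA1 (322 FPKM) the heat shock list, and ACSL3 (94.5 FPKM), FADS1, ACACA and SREBF1 the fatty acid list. HLA-DPA1 was detected in 36 of 96 cells, CD74 in 41 of 96 cells, HLA-DMA in 22 of 96 cells and HLA-DPB1 in 17 of 96 cells. PRAME had a median of 78.2 FPKM, and CSAG1 (84.2 FPKM), MAGEA6 (42.3 FPKM) and MAGEA3 (31.6 FPKM) are uncertain because near-identical copies can share fragments.

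**Figure D3:**
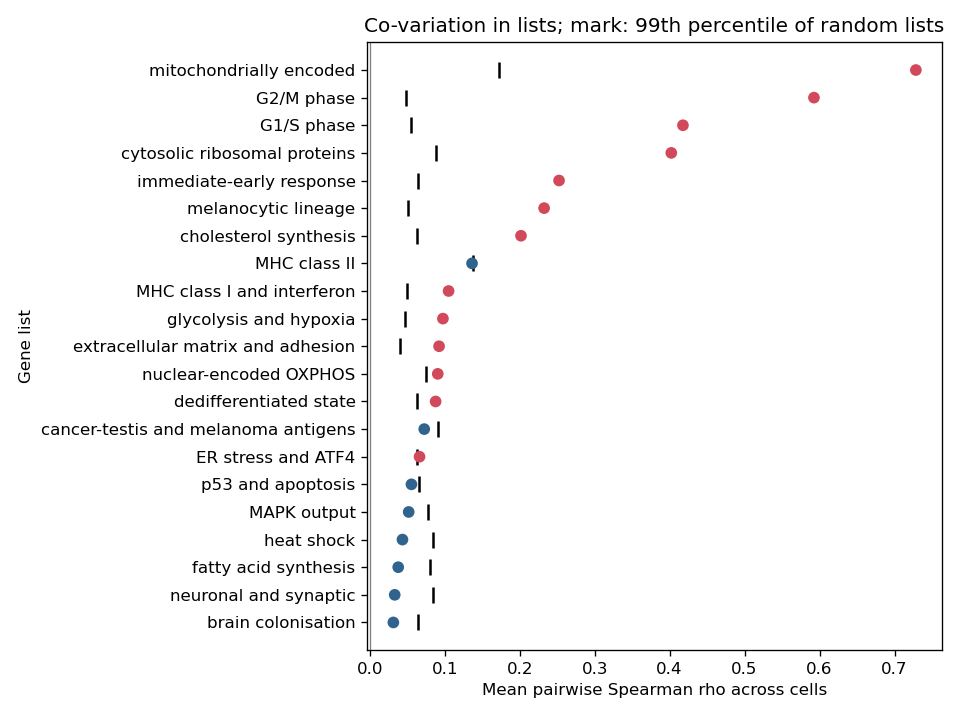
Mean pairwise Spearman rho across 96 cells for each gene list (points), with the 99th percentile of 10000 matched random lists as a vertical mark. Red points lie above percentile 99, from mitochondrially encoded genes at 0.728 down to ER stress genes at 0.0664, and blue points do not.

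Cells with higher melanocytic scores had lower scores for the dedifferentiated state (Pearson r -0.523, Spearman rho -0.563, and r -0.571 without the 2 cells farthest on the x axis), and this r was below that of all 10000 matched random list pairs. In the 86 deeper cells r was -0.477. The melanocytic score also ran opposite to extracellular matrix and adhesion (r -0.493, rho -0.520, r -0.557 without those cells), and the dedifferentiated score ran with it (r 0.711, rho 0.689, r 0.689) after their shared genes were left out. G1/S and G2/M scores ran together (r 0.360, rho 0.445, r 0.362 without the 2 farthest cells). G2/M and MAPK output ran opposite (r -0.366, rho -0.361, r -0.333), although the MAPK output list did not itself stand apart in co-variation (mean rho 0.0520). With the genes detected regressed out, with a pseudocount of 10 and with the marker filter without the oligodendrocyte list, neither of these last pairs stood apart (r 0.301, 0.328 and 0.330 for G1/S with G2/M, and -0.270, -0.360 and -0.325 for G2/M with MAPK output). Without a gene filter G2/M with MAPK output did not either (-0.319). These were 5 of 18 pairs fixed in advance, and the other 13 stayed within the random range, although immediate-early response with heat shock (r 0.330) left it in TPM (0.3502). Among those, OXPHOS and mitochondrially encoded scores gave r -0.415 in all cells, rho 0.101, and r 0.305 in deeper cells, so its sign rested on the shallow cells.

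**Figure D4:**
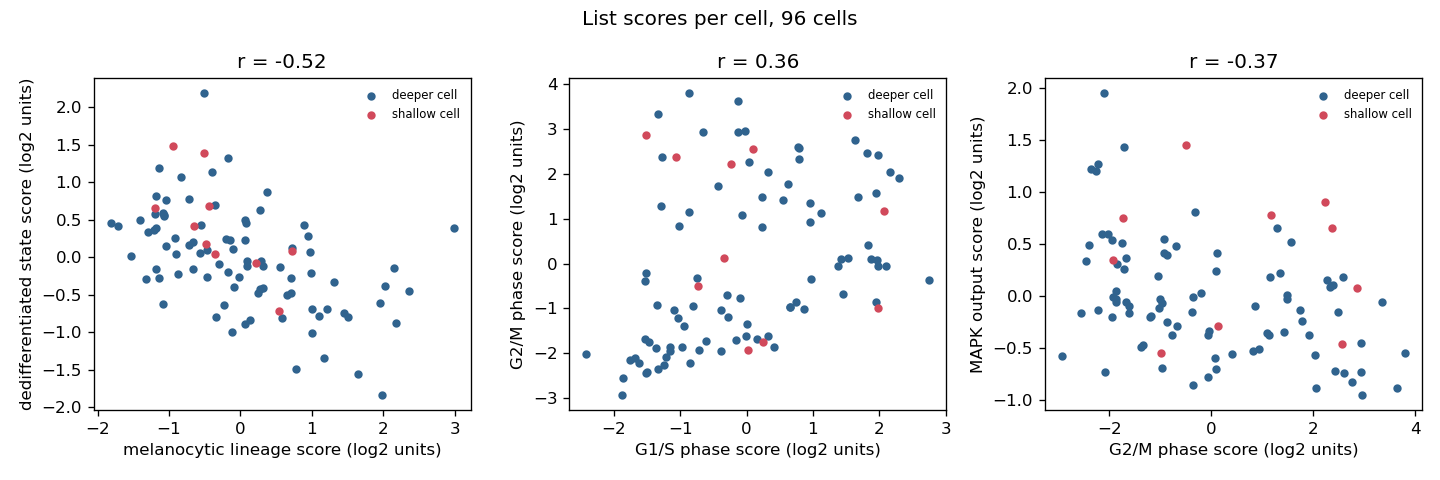
List scores in log2 units per cell, for melanocytic against dedifferentiated, G1/S against G2/M, and G2/M against MAPK output, with deeper cells in blue and shallow cells in red. The Pearson r over 96 cells was -0.523, 0.360 and -0.366.

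Genes outside the melanocytic list that ran most closely with its score were APOE (0.760), APOC1 (0.731), LGALS3 (0.726), TSPAN7 (0.715), IRF4 (0.683), MBP (0.676), RNASE1 (0.662), ASAH1 (0.650), PIR (0.634), SNCA (0.633), with Spearman rho in parentheses. APOE (ENSG00000130203.9, chromosome 19, 44905754 to 44909393) and APOC1 are neighbouring apolipoprotein genes, and IRF4 is a transcription factor of pigment cells. The lowest rho were those of PDIA6 (-0.693), HSP90B1 (-0.681), MYDGF (-0.608), PPIB (-0.605), ASPH (-0.601), TINAGL1 (-0.598), SSR2 (-0.595), NGFR (-0.593), PDIA4 (-0.591), PAX8 (-0.582). PDIA6 (ENSG00000143870.12, chromosome 2, 10783391 to 10837977), PDIA4, HSP90B1 and PPIB encode folding proteins of the endoplasmic reticulum.

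The G2/M score was followed by PBK (0.878), PRC1 (0.869), KIF2C (0.857), HMGB1 (0.840), APOBEC3B (0.839), CDKN3 (0.833), KIF4A (0.831), DEPDC1 (0.828), CEP55 (0.827), GTSE1 (0.826), among them mitotic kinesins and spindle proteins. Its lowest rho were A1BG (-0.556), EEF1A1 (-0.544), IFITM3 (-0.523), CRYAB (-0.520), S100A6 (-0.517), FTL (-0.506), RPL12 (-0.497), IFITM2 (-0.490), CST3 (-0.490), RPL13A (-0.487), and RPL12, RPL13A, EEF1A1 and FTL have processed copies that make their values uncertain, as the similarity of IFITM2 and IFITM3 does for these. The dedifferentiated score was followed by TINAGL1 (0.623), VGF (0.599), ZYX (0.588), MSMP (0.566), RGP1 (0.555), RRBP1 (0.534), LCN1 (0.530), PDIA4 (0.502), MYDGF (0.501), PPIB (0.4998), and ran opposite to GPNMB (-0.628), TYR (-0.594), DCT (-0.553), PMEL (-0.551), SNX10 (-0.541), MITF (-0.536), METTL9 (-0.525), SDCBP (-0.522), TNFRSF14 (-0.514), APOC1 (-0.504). RGP1 and MSMP overlap on opposite strands of chromosome 9 (RGP1 35749287 to 35758575, MSMP 35752990 to 35756613), and fragments of the pair cannot be told apart without strand.

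MSMP, a secreted microseminoprotein (ENSG00000215183.4), had the highest FPKM in 19 cells, a median of 1966 FPKM, interquartile range 74.8 to 18507, and a highest value of 178275 FPKM. It exceeded 10000 FPKM in 34 cells and was under 100 FPKM in 29 cells. MT-RNR2, a mitochondrial ribosomal RNA, was the highest gene in 60 cells.

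The 25 genes with the most spread for their level in all 96 cells were TMSB4X, WDR6, MKI67, RN7SK, SPI1, EPHA2, ANKRD17, AL139099.4, ZFAND5, ATP13A1, GTPBP2, HIST1H2BB, SNORD17, MYO19, a copy of RF00100, ID2, HIST1H2BG, CTSZ, RN7SL731P, TGFA, AC127024.7, HIST1H4H, CD68, TSC2, AP000525.1. Of these, 20 had their highest value in cell 9, and small RNA and histone genes among them have near-identical copies. Without cell 9, 6 of the 25 were shared. Among lists, G2/M (median residual 0.367 log10 units) and mitochondrially encoded genes (1.46, but 0.532 in deeper cells) stood apart, and in the 86 deeper cells the melanocytic list did too, as did the brain colonisation list (melanocytic 0.309, against 0.119 in all cells). In TPM the melanocytic, G1/S, ER stress, MHC class I and interferon, and dedifferentiated lists did as well, with the variance of log2 the melanocytic and G1/S lists did, and without a gene filter the melanocytic list did (0.241). With the variance of log2 in deeper cells, MHC class II was added, and mitochondrially encoded genes no longer stood apart. Clustering on the most spread genes put cell 9 alone and the other 95 cells together (mean silhouette 0.800). In TPM cell 9 was not alone but in a cluster of 5 cells, and the mean silhouette was 0.159, with 4 clusters. In the 86 deeper cells the highest mean silhouette was 0.152, with 6 clusters, and no cluster was named. Without cell 9, 94 cells were together and a single other cell stood alone.

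All 96 cells had at least 4 of the 9 melanoma cell markers. Markers of the oligodendrocyte lineage reached 3 or more in 89 cells, through CNP (median 46.1 FPKM, 96 of 96 cells), MAG (80.8 FPKM, 95 of 96 cells) and CLDN11 (86 of 96 cells), while MOBP and OLIG2 were listed at 0 in every cell. Microglia or macrophage markers did so in 33 cells (34.4%, interval 25.0 to 44.8%), led by LAPTM5 (60 of 96 cells) and AIF1 (38 of 96 cells), with C1QA, CX3CR1 and P2RY12 listed at 0 in every cell. Neuron (GAD1 in 43 of 96 cells, SYT1 in 41 of 96 cells) and endothelium markers (FLT1 in 47 of 96 cells, ESAM in 23 of 96 cells) reached that number in 2 cells each and astrocyte markers (AGT in 30 of 96 cells, SLC1A3 in 4 of 96 cells) in 1 cell. No cell did so for pericytes (RGS5 in 60 of 96 cells, ACTA2 in 19 of 96 cells), T cells (TRAC in 40 of 96 cells, CD3E in 6 of 96 cells), ependyma (TTR in 7 of 96 cells) or erythroid cells (HBA2 in 3 of 96 cells, HBA1 in 1 cell). Counting any value above 0 as detected, 9 cells reached that number of markers for pericytes and 2 for astrocytes. At 5 FPKM 0 cells did for neurons, endothelium or astrocytes. Among the 86 deeper cells, 0 did for endothelium.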

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

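No paired analysis was possible because all cells belong to 1 group. The restrictions to deeper cells, to cells other than cell 9 and to cells filtered on markers without the oligodendrocyte list were chosen after seeing the data. The planned marker filter left 4 cells and was not run, under a minimum of 20 set after that number was seen, and keeping all 96 cells or those with at least 4000 genes removed none and so tested nothing. The melanocytic and dedifferentiated scores ran opposite under every alternative run, with r from -0.573 to -0.477, past the limit each time. The number of co-varying lists lay between 11 and 14, not counting pseudocounts, which cannot change a rank correlation between genes. G1/S with G2/M fell within the random range with genes detected regressed out (r 0.301), with a pseudocount of 10 (0.328) and with the marker filter (0.330), and the pairs that stood apart then numbered 3 in each, against 5. The median number of genes detected became 9698 for any value above 0 and 6996 at 5 FPKM, by construction. The 10 genes with the lowest rho to the melanocytic score had a median rho of -0.693 with the marker filter, against -0.600. The most spread genes depended on the setting. Of the 25, 3 were shared in deeper cells, 6 without cell 9, 10 in TPM, 14 without a gene filter, 4 with the variance of log2 and 2 with that variance in deeper cells. Over-dispersed lists numbered 4 in deeper cells, 4 with the variance of log2, 4 with both, 7 in TPM and 3 without a gene filter, against 2. Clusters numbered 6 in deeper cells and 4 in TPM, against 2. Apart from detection, the cause was not tested. Among single lists, pairs and genes, not counting the results given so far or settings that could not move a value, 604 kept their side or stayed within their spread, 11 no longer stood apart, 17 newly did and 19 moved. No value that stood apart changed sign, while OXPHOS with mitochondrially encoded genes, which did not stand apart, went from r -0.415 to 0.305 in deeper cells.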

Other observations

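The tests of shallow libraries, of depth against MSMP, of ER genes, of ribosomal protein genes and of MSMP fragments counted for RGP1 were chosen after the result was seen. No biological explanation was tested against a group, since the design gives a single group.

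Of the 25 most spread genes of all 96 cells, 24 had their highest value in a shallow cell, in which 1 fragment is worth many FPKM, and 20 of these had it in cell 9. All of the shallow cells concerned were also above 30% mitochondrial, and 0 genes peaked in the 5 shallow cells with a low mitochondrial share. In the 2 high-mitochondrial cells that were not shallow, 0 genes peaked, which had been set as evidence against the mitochondrial share. That does not decide it, as the 24 peaks in shallow cells lay only in cells with both properties. The remaining gene, TGFA, peaked in cell 93, which lay under both limits. Its fragment value of 1.91 FPKM was however the highest of the 86 deeper cells, just under the limit of 2 FPKM. Apart from those in cell 9, the peaks in shallow cells lay in cell 66. Cells 9 and 66 also had the highest FPKM totals, 15646628 and 10473756, against a median of 831949. In TPM, where totals are equal, only some of the 25 genes stayed among the most spread. A high fragment value, a high mitochondrial share and a high FPKM total therefore cannot be told apart as sources of these genes.

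The opposite course of melanocytic and dedifferentiated scores (r -0.523) was kept when possible technical sources were regressed out. It was -0.521 after regression on the fragment value and genes detected, and -0.535 after regression on the mitochondrial share. After regression on both cell cycle scores it was -0.545, and each r lay below the random range. Linear trends with these measures are therefore argued against as its whole source, while animal and site in the brain stay open, as the labels name neither for any cell.

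MSMP spanned 11.2 to 178275 FPKM. Fragments of RGP1, which overlaps it, were tested as a source. The log2 ratio of MSMP to RGP1 had an SD of 2.99 and a median of 10.7 over 59 cells, so RGP1 as listed was far below MSMP. That SD lay above the bound set against this source, but it mixes cells with high and low MSMP. The listed values may also reflect how shared fragments were divided between the genes. In 47 cells with MSMP at 1000 FPKM or more and RGP1 detected, the median log2 ratio was 10.8. RGP1 at its listed level is thus argued against as the main source in those cells, while the values in the lowest cells stay open. Depth, as read from the fragment value, is argued against (rho 0.196). In the other direction, RGP1 ran with MSMP (rho 0.781), and MSMP fragments might have been counted for RGP1. In 47 cells with high MSMP the ratio had an SD of 1.197, between the bounds set for and against, so this cannot be told apart from a shared course, and RGP1 should not be read as a separate follower. The description of this pattern was corrected after the values were seen, from near 0 to below 100 FPKM, with the bounds left as they were.

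A hypothesis from the followers of the melanocytic score was that genes of protein entry and folding in the endoplasmic reticulum run opposite to it. On 26 such genes that were not among the named followers, r was -0.622 (rho -0.714), below all matched random pairs drawn, and -0.712 in deeper cells. The list was taken apart after the 26 had been tested together. The 12 folding enzymes and chaperones alone gave r -0.617 (rho -0.673), also below all random pairs and past the bound set for them. Both sets varied together (mean rho 0.125 for the 26 and 0.116 for the 12), while random lists were matched on mean level only. The hypothesis also came from these cells, so the values extend the pattern to further folding genes without testing it independently. The 14 translocation and glycosylation genes alone gave r -0.3497 (rho -0.493), within the random range. Without the 2 cells farthest on their score r was -0.487, past the random limit of -0.392 for all cells. In deeper cells it was -0.572, below the random range, so these genes were left undecided. The same test for lysosomal genes, predicted to run with the melanocytic score, gave r 0.196, within the random range but above 0, so it was left undecided. Ribosomal protein genes, predicted to run opposite to G2/M, gave r -0.341 in all cells, within the random range, and -0.571 in deeper cells, below it, so this stays undecided.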
